A study of Mus musculus with 12 samples.

How the data were processed

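Spleens of female C57BL/6 mice, 5 weeks old per the labels, were profiled on single-colour Illumina mouse arrays with 45281 probes. Mice received either 300 µL of PBS or 30000000 cells of Mycobacterium avium subsp. paratuberculosis (MAP, strain ATCC 19698) in the peritoneal cavity, and 5 mice of each treatment were sampled at 3, 6 and 12 weeks. Each of the 6 groups (control or infected at 3 sampling times) held 2 arrays, so 12 arrays in all. The labels do not say whether the 2 arrays of a group stand for separate mice, pools of mice or repeats of the same RNA. The p-values here therefore measure only the spread between these arrays, which may be technical. Per the labels' protocols, RNA was extracted with the RNeasy Mini kit, digested with DNase, checked on a Bioanalyser, then amplified and biotin-labelled with the MessageAmp kit.

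The intensity values deposited by the authors are average bead intensities per probe, not normalized between arrays and never negative. Each intensity column is followed by a detection p-value, per the file headers, which runs from 0 to 1 in equal steps of the kind given by 936 negative control probes. The authors also deposited a processed table on what its values show to be a log2 scale; R 3.0.2 is the only tool named in the submitters' processing notes, and the method behind the table is not stated. Its 12 columns share nearly 1 distribution with a median of 6.96. Joined by probe identifier, the columns of the authors' log2 table and the non-normalized intensities correlated at only 0.018 to 0.040 across probes, whereas the sorted values correlated at 0.999 or more. Transcripts that every spleen holds in abundance lay where they belong in the intensity table (Actb at the 99.9th percentile, Gapdh 99.0, B2m 99.8, Cd74 100.0) but not under the same identifiers in the processed table (Actb 31.9, Gapdh 10.8, B2m 14.0, Cd74 65.6). No gene name was therefore taken from the processed table, and it served only for counts over all of its unnamed probes, which departs from the planned use of the same genes. Its direction and any centring per probe could not be settled probe by probe.

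The non-normalized intensities were corrected for background and quantile-normalized with neqc in limma 3.58.1 (R 4.3.3), which fits the background from the detection p-values and adds an offset of 16 before taking log2. Gene symbols came from the platform annotation table: 34885 probes had 1 symbol, 18 had several and 10378 had none, and matching by Entrez identifier changed 0 symbols. Probes with several symbols were not named. Probes with a detection p under 0.05 on at least 2 of the 12 arrays were kept, which left 20936 probes, 17526 of them with a symbol. For each gene the probe with the highest mean was used, giving 11414 genes tested. Of these, 4242 had more than 1 probe past the filter. Between 37.77% and 40.56% of probes were detected per array, and median intensity per array lay between 116.7 and 133.9. The number of arrays, 2 per group, limits the precision of every value.

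A mean was fitted for each group with limma's lmFit over all 12 arrays, leaving 6 residual degrees of freedom, and eBayes added 2.48 prior degrees of freedom. Contrasts were infected minus control at each week, their average, the pairwise differences of these effects between weeks, a moderated F-test over those differences, and a moderated F-test over the 3 control groups. All tests were two-sided, p-values were adjusted by Benjamini-Hochberg over the 11414 genes, and genes with an adjusted p under 0.05 are referred to as called. Changes are log2 differences of normalized intensity, values after ± are standard errors of the fit, and n is 2 arrays per group throughout. Quantile normalization gives all arrays a common distribution, so a change is relative to the other transcripts of a sample. It is not an amount per spleen, and a lower value can mean a smaller share of the RNA. Where a probe was detected on neither array of a group, the fold is given as a lower limit ("at least N-fold"), taken against the lowest detected signal on those arrays, or the probe's own signal if that was higher.

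The 35 gene lists (704 genes) were tested with limma's camera, with an inter-gene correlation of 0.01, against all other genes tested, adjusted by Benjamini-Hochberg over the lists of a comparison. Of the listed genes 521 were measured, 62 had no named probe and 121 did not pass the filter. Lists with fewer than 5 measured members (Th17 and Th2, 4 each) were not tested, which left 33. Camera with an estimated correlation and limma's fry were run beside it. List p-values below are with the preset correlation unless stated. It treats the genes of a list as nearly independent, and its p-values can be far smaller than with an estimated correlation. For erythroid genes at 3 weeks against the controls of the other weeks, the camera adjusted p was 1.18e-19 with the preset and 0.00371 with the estimated correlation. The genes named in the text were, per comparison, the 10 with the largest positive and the 10 with the largest negative change among called genes whose infected arrays all lay on the same side of the control arrays of the same week, up to 4 members with the smallest p of every called list, 16 fixed genes of host defence (12 of them measured), and the 10 with the smallest p of each F-test. The lists, the naming rule, the tests and the alternative settings were chosen before the data were examined. Lists of 40 liver genes and 10 lymph node vessel genes were added afterwards.

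Array numbers 1 and 2 recur in the labels of all groups. The differences between the arrays of a group correlated across genes at 0.661 to 0.751 in all 15 pairs of groups, all above 0.1, and the second principal component (12.9% of the variance) separated array 1 from array 2 in each group. The numbers were therefore taken to mark a shared step, although the labels do not name one. A fit with the array number as a block was run as an alternative, and its values are given where it changed the call of a named result or moved a count by more than 1.5 times. Other alternatives were no background correction, normexp with an offset of 50, scaling to a common median, cyclic loess, no probe filter, a filter at a detection p of 0.01 on both arrays of a group, all probes in place of a single probe per gene, the arrays of the week alone, array weights, a trended and robust prior, and leaving out each array in turn. Leaving out an array unbalanced the array numbers of its group, and those fits had no block. The shared difference by array number therefore enters their values. No slide block was run, because no slide information was used. Comparisons against the controls of the other weeks, without the 6-week or the 12-week arrays, and on group means were added after seeing the data.

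The fit and the list test were run on simulated values for infection at 3 weeks with 11414 genes. They recovered 27 of 50 genes changed by a log2 of 1 (54%), 42 of 50 at 2 (84%), 49 of 50 at 3 (98%) and 50 of 50 at 4 (100%), with 12 unchanged genes among 180 called and 0 sign errors. Of the lists, 1 was called, the shifted one. The simulation started from normalized gene values, so normalization, the probe filter and the choice of probes were not tested. Its noise was independent between genes, without the shared difference by array number, and far fewer genes changed than were called in the data. The list test was therefore not tried on correlated genes. As a check of the labels, 8 probes of Y-linked genes were read, and none was detected on more than 1 of the 12 arrays of these female mice. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.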

Results

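Transcript levels were measured in the spleens of mice given MAP, the bacterium of Johne's disease, and of mice given PBS, at 3, 6 and 12 weeks after injection into the peritoneal cavity. Each of the 6 groups had 2 arrays, 6 from infected and 6 from control mice, and the labels do not say whether both arrays of a group hold different mice, so the spread between them need not be that between mice. Between 37.77% and 40.56% of the 45281 probes were detected per array, and 11414 genes were tested. The first principal component held 67.7% of the variance and parted infected from control arrays. Infected arrays lay at 51.88 to 59.11 on it at 3 and 6 weeks and at 15.24 to 15.91 at 12 weeks, and the control arrays lay below 0 at every week. Normalized log2 values correlated at 0.9823 to 0.9878 within groups, and the highest correlation between arrays of different groups was 0.9908. Log2 changes below are on the scale of the chosen background correction: without it 151 of the called values of genes and lists moved by over 1.5 times, and with the larger offset 83.

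The comparison at 3 weeks asks which splenic transcripts differed early after infection. Relative to other transcripts, infected spleens held far more transcripts of Saa3, of interferon-inducible genes and of genes of neutrophil granules, red cell precursors and the cell cycle. They held relatively fewer transcripts of B cells, T cells and NK cells. Saa3, an acute-phase serum amyloid A protein, was 318-fold higher (log2 change 8.31 ± 0.19, limma adjusted p = 1.5e-07, 13.67 against 5.36). Gbp2b, an interferon-induced guanylate-binding protein, was 65.7-fold higher (6.04 ± 0.51), and Acod1, the enzyme that makes itaconate in activated macrophages, was at least 30.6-fold higher (5.42 ± 0.11). The strongest falls were in Ly6d, a surface protein of B cells (12.3-fold lower, -3.62 ± 0.17), and in Klra7, a Ly49 receptor of NK cells (11.3-fold lower, -3.50 ± 0.14).

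The other large increases at 3 weeks were in Apol11b of the apolipoprotein L family (53.8-fold), Rhag, the Rh-associated glycoprotein of red cells (32.0-fold), Abcg4, a sterol transporter (25.4-fold), Erfe, the erythroblast hormone that lowers hepcidin (at least 24.2-fold), and Pdilt (at least 19.1-fold). Metap2 (at least 29.0-fold) and Sox6, a transcription factor of erythroid cells (at least 24.5-fold), belong here too, but their other probes showed log2 changes of only 1.41 and 0.38. Falls of 8-fold or more included Klra4, a further Ly49 receptor (-3.44 ± 0.21), Cd209b, the lectin SIGN-R1 of marginal zone macrophages (-3.42 ± 0.23), and the B cell genes Vpreb3 (-3.41 ± 0.22), Blk (-3.10 ± 0.12) and Fcer2a, which encodes CD23 (-3.04 ± 0.34). Gpr183, the receptor that positions B cells in follicles, fell by 3.06 ± 0.13, Ell3 by 3.20 ± 0.10 and 4930426D05Rik by 3.04. In all of these genes both infected arrays lay on the same side of both control arrays.

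Among lists of host defence genes at 3 weeks, 24 of 26 measured IFN-gamma-inducible genes rose, 1 fell and 1 was not called (median 1.97, or 1.86 with undetected members at their limit, camera adjusted p = 1.77e-14). They included the chemokine Cxcl9 (3.33 ± 0.10), Upp1 (3.13 ± 0.14) and the ubiquitin-like modifier Ubd (2.93 ± 0.14). Type I interferon-stimulated genes rose in 13 of 26, with 2 lower (median 0.49, adjusted p = 0.00177). Isg15 (3.13 ± 0.20) and Rsad2, which encodes viperin (2.18 ± 0.12), rose most clearly, while Sp100 fell by 1.15 ± 0.13. Inflammatory cytokines and chemokines rose in 12 of 21, with 1 lower (median 0.78, adjusted p = 0.000149), among them Ccl8 (at least 8.87-fold) and Il27 (at least 3.04-fold). Pattern recognition genes rose in 12 of 23, with 1 lower (median 0.46, adjusted p = 0.000149). Clec4e, the receptor Mincle for mycobacterial cord factor, was at least 15.4-fold higher. Of 10 complement genes 5 rose, including C1qa, C1qb and C1qc (1.36 to 1.72; median 0.33, adjusted p = 0.00177, adjusted p = 0.186 with an estimated correlation). Of 11 oxidative burst genes 6 rose and 2 fell (median 0.49, or 0.28 with undetected members at their limit, adjusted p = 0.0436), but this call ended with an estimated correlation (adjusted p = 0.108) and with the array number as a block (0.0687). It was also lost, at 0.05 to 0.055, without background correction, with the larger offset, stricter detection or a trended prior, and without any 1 of 4 arrays. Nos2, the inducible nitric oxide synthase, was at least 2.40-fold higher (1.74 ± 0.15).

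Myeloid lists rose together at 3 weeks. Monocyte and inflammatory macrophage genes rose in 12 of 19, with 1 lower (median 1.24, or 1.19 with undetected members at their limit, adjusted p = 5.53e-07). Among them were the Fc receptors Fcgr4 (2.84 ± 0.13) and Fcgr1 (2.49 ± 0.14) and the phagosomal metal transporter Slc11a1 (1.48 ± 0.12). Of 14 genes of granuloma and alternatively activated macrophages, 10 rose and 2 fell (median 0.92, adjusted p = 0.00177), led by Gpnmb (4.45 ± 0.11) and Trem2 (at least 7.76-fold). Of 19 neutrophil granule and precursor genes, 17 rose and 2 fell (median 2.91, adjusted p = 1.51e-12), for example cathepsin G, Ctsg (3.78 ± 0.14), and myeloperoxidase, Mpo (3.35 ± 0.12). Mature neutrophil genes rose in 11 of 15, with 1 lower (median 1.55, adjusted p = 3.45e-06), led by haptoglobin, Hp (4.25 ± 0.24), and lipocalin 2, Lcn2 (3.69 ± 0.18). Red pulp and marginal zone macrophage genes went both ways, with 10 of 18 higher and 3 lower (median 0.65, adjusted p = 0.0183). That call was lost with an estimated correlation (adjusted p = 0.102) and with the array number as a block (adjusted p = 0.0534). It joined a rise of Mertk, a receptor for engulfing dead cells (2.00 ± 0.15), and Spic, a transcription factor of red pulp macrophages (1.45 ± 0.11), to the fall of Cd209b.

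Erythroid genes had the largest median of the lists called at 3 weeks, with 22 of 24 higher and 0 lower (median 3.53, adjusted p = 1.38e-19). Trim10 rose by 3.59 ± 0.13, the transferrin receptor Tfrc by 3.46 ± 0.11 and the transcription factor Nfe2 by 3.35 ± 0.11. Of 30 cell cycle genes 28 rose and 0 fell (median 2.11, adjusted p = 1.62e-18), including Prc1 (2.58 ± 0.12), survivin, Birc5 (2.52 ± 0.13), and Cdk1 (2.47 ± 0.13). Megakaryocyte and platelet genes rose in 6 of 15 (median 0.54, adjusted p = 0.00209), such as Selp, which encodes P-selectin (1.05 ± 0.14), and Gp9 (1.20 ± 0.19). Adjusted over the list alone, the counts at 3 weeks changed to 13 higher and 3 lower for type I interferon, 13 higher for pattern recognition, 15 higher for monocytes, 3 lower for granuloma, 7 higher for megakaryocytes and 29 higher for the cell cycle, and those of the other lists given for this week were as above unless stated.

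Lymphoid lists fell at 3 weeks relative to the other transcripts, and amounts per spleen were not measured. Of 21 B cell genes 20 fell and 0 rose (21 lower adjusted over the list alone; median -2.61, adjusted p = 8.5e-15), among them Fcrla (-2.94 ± 0.11), Cd79b, a chain of the B cell receptor (-2.81 ± 0.13), and the IgM receptor Fcmr (-2.69 ± 0.11). Of 15 T cell genes 14 fell (median -1.46, adjusted p = 7.2e-08), including Cd8b1 (-2.21 ± 0.11) and the CD3 chains Cd3d, Cd3e and Cd3g (-1.96, -1.41 and -1.61). Of 10 naive T cell genes 8 fell (median -1.75, or -1.52 with undetected members at their limit, adjusted p = 0.000113), such as the homing receptor Ccr7 (-2.21 ± 0.17) and Klf2 (-2.36 ± 0.15). NK cell genes fell in 9 of 11, with 1 higher (median -1.51, or -1.40 with undetected members at their limit, adjusted p = 0.000465). Of 22 genes of stroma, endothelium and smooth muscle, 12 fell and 1 rose (13 lower adjusted over the list alone; median -0.80, or -0.78 with undetected members at their limit, adjusted p = 0.00113, adjusted p = 0.236 with an estimated correlation). They included smooth muscle actin Acta2 (-1.77 ± 0.13), desmin, Des (-1.68 ± 0.12), and the T zone chemokine Ccl21a (-2.34 ± 0.24). Of 6 adipose genes, markers of neighbouring fat, 3 fell (median -0.82, or -0.57 with undetected members at their limit, adjusted p = 0.0308). This call was lost with an estimated correlation (adjusted p = 0.102) with the block (adjusted p = 0.0611) without the probe filter (median -0.09, adjusted p = 0.10) and without background correction (adjusted p = 0.053). The fat cell hormone Adipoq lay at 7.20 and 7.24 on the 3-week control arrays and was at least 3.57-fold lower in infected spleens.

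At 3 weeks the fit called 4197 genes (36.8%), 1916 higher and 2281 lower, of which 1059 rose and 946 fell by 2-fold or more. Which direction held more genes depended on the scaling, with 2238 higher and 2044 lower under cyclic loess and 1727 and 2934 under median scaling. With the array number as a block the count was 6718, and of the 33 lists tested 20 were called (14 up, 6 down), 15 of them also with an estimated correlation. The block ended 3 of these calls and added lysosome genes (median 0.26, adjusted p = 0.0274). Against the controls of the other weeks, a comparison added after seeing the data, the fall of the stromal list and the rise of the oxidative burst list were lost (adjusted p = 0.2 and 0.071), and Cxcl12, a stromal chemokine, turned from -1.30 ± 0.10 to 0.33. In the same comparison the medians of the megakaryocyte (1.59, or 1.40 with undetected members at their limit, 13 of 15 higher), red pulp (1.92), complement (1.48), granuloma (1.41) and mature neutrophil lists (2.34, or 2.24 at the limit) were larger and that of the NK list (-0.97, or -0.65 at the limit) was smaller in size. Among genes, Lcn2 (at least 94-fold), Retnlg (at least 45-fold), S100a8 (5.87), Trim10 (5.51), Camp (4.69), Rsad2 (3.50), Cd14 (3.28), C1qa to C1qc (2.21 to 2.78), Spic (2.46), Slc11a1 (2.42), F2rl2 (2.29), Gp9 (2.08) and Selp (1.67) rose more, and Klra4 (-1.89) and Adipoq (at least 2.33-fold) fell less. The complement median was 0.19 under median scaling, and the adipose median -1.24 without control 12 wk replicate 1. Without the probe filter the mature neutrophil and NK medians were 0.81 and -0.89. The basophil list was not called at 3 weeks (median 0.312, adjusted p = 0.0963), but it was with stricter detection (0.039), without either 3-week control array (0.037 and 0.02) and against the controls of the other weeks (0.72, or 0.60 at the limit, adjusted p = 0.0023).

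**Figure D1:**
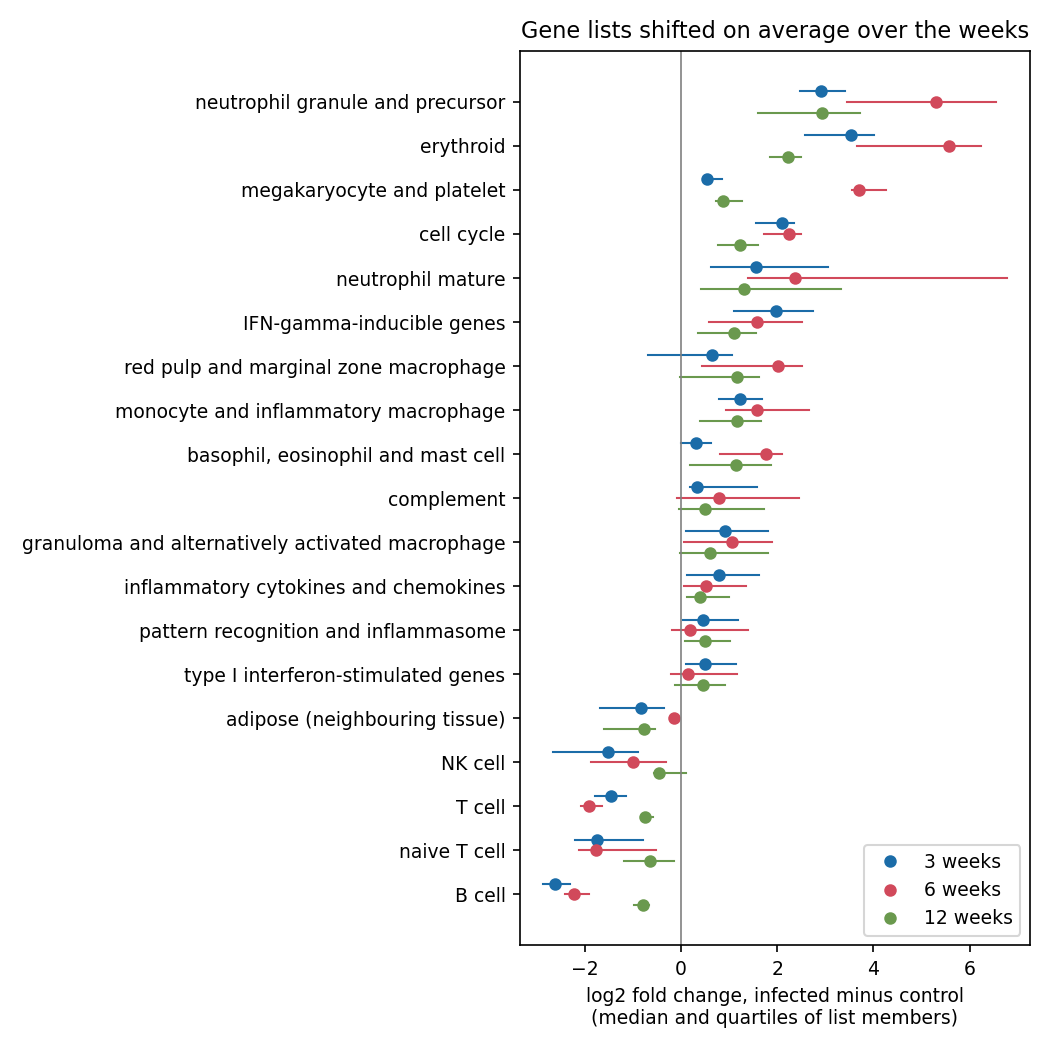
Median log2 fold change (dots) and quartiles (bars) of the measured members of each gene list that was called for infection averaged over the weeks, infected minus control, at 3, 6 and 12 weeks. Erythroid genes shift by a median of 3.53, 5.57 and 2.22, and B cell genes by -2.61, -2.21 and -0.79.

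At 6 weeks the same comparison was made in mice of the next sampling. Against the controls of that week, the largest increases were in genes of neutrophils and of red cell precursors, and B and T cell genes stayed lower. Lipocalin 2, Lcn2, an iron-trapping protein of neutrophils, was at least 212-fold higher (log2 change 8.30 ± 0.18, limma adjusted p = 2e-08). Car1, the carbonic anhydrase of red cells, was 202-fold higher (7.66 ± 0.13, 13.08 against 5.43), and the calprotectin chains S100a8 and S100a9 were 188-fold and 180-fold higher (7.55 ± 0.14 and 7.49 ± 0.49). The 6-week control arrays held the lowest levels of Car1, S100a8 and Lcn2 among the controls. Car1 lay at 5.43 there against 10.06 and 8.78 in the 3-week and 12-week controls, and S100a8 at 6.40 against 10.85 and 8.65. Lcn2 lay at 5.06 and 4.65 on these arrays, against 8.85 and 8.68 at 3 weeks and 6.58 and 6.14 at 12 weeks. Against the controls of the other weeks, a comparison added after seeing the data, Saa3 and Gbp2b rose more than Lcn2, Car1 and S100a8.

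Trim10 (174-fold), the erythroid nuclear protein Hemgn (153-fold), Apol11b (147-fold) and lactoferrin, Ltf (125-fold) followed at 6 weeks, with the neutrophil granule protein Ngp (at least 124-fold) and Saa3 (at least 113-fold). Downward, Psmb1, a proteasome subunit, fell by 3.58 ± 0.21 and Lrat, which esterifies retinol, by 3.26 ± 0.23. Fcer2a was lower by -3.21 ± 0.34, the interleukin 7 receptor Il7r by -2.97 ± 0.54, Igfbp5 by -2.96 and Gpr183 by -2.86 ± 0.13. Crip3, Slc16a5 and Trnp1 were 7.86-fold, 7.34-fold and 7.10-fold lower, though another probe of Crip3 showed only -0.74, and Insm1 was at least 5.01-fold lower.

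Erythroid genes rose in 23 of 24 at 6 weeks (0 lower; median 5.57, adjusted p = 1.69e-22), among them Alas2, the first enzyme of erythroid haem synthesis (5.51 ± 0.10), and Nfe2 (6.14 ± 0.11). In the 6-week controls 22 of these 24 genes lay below the mean of the other controls, by a median of -2.19 over the list, and in infected spleens the median difference from the other weeks was 0.38. Neutrophil granule genes rose in 17 of 19, with 2 lower (median 5.29, adjusted p = 1.12e-14), such as Camp, the cathelicidin (6.68 ± 0.11), and Mpo (6.54 ± 0.12). Of these 19 genes, 17 lay lower in the 6-week controls (median -0.84), and 18 lay higher in 6-week infected spleens (median 1.17). Mature neutrophil genes rose in 14 of 15, with 1 lower (median 2.37, adjusted p = 6.31e-09), including Retnlg (at least 68.6-fold) and Hp (at least 90.9-fold). Megakaryocyte and platelet genes rose in 14 of 15 (median 3.69, adjusted p = 2.39e-12). F2rl2, the thrombin receptor PAR3, rose by 4.66 ± 0.12, Mmrn1 was at least 16.3-fold higher and the platelet tubulin Tubb1 rose by 3.52 ± 0.11. All 15 lay lower in the 6-week controls (median -1.29) and higher in the 6-week infected spleens (median 1.79) than at the other weeks.

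Of 18 red pulp and marginal zone macrophage genes 12 rose and 3 fell at 6 weeks (median 2.02, or 1.88 with undetected members at their limit, adjusted p = 1.94e-05), led by the mannose receptor Mrc1 (4.68 ± 0.13), Treml4 (2.81 ± 0.14) and the iron exporter Slc40a1 (2.30 ± 0.11). In the 6-week controls 17 of the 18 lay lower than in the other controls (median -0.84), and infected spleens differed from the other weeks by a median of 0.17. Monocyte genes rose in 12 of 19, with 2 lower (median 1.59, adjusted p = 1.88e-06), including coagulation factor F13a1 (4.58 ± 0.18), Fcgr4 (3.94 ± 0.13) and the endotoxin co-receptor Cd14 (3.07 ± 0.12). Granuloma genes rose in 8 of 14, with 1 lower (median 1.06, adjusted p = 0.00127), with the chitinase-like Chil3 at least 54.7-fold higher and Gpnmb at 2.83 ± 0.11. Basophil, eosinophil and mast cell genes rose in 7 of 9 (median 1.77, or 1.49 with undetected members at their limit, adjusted p = 3.48e-05), among them the basophil protease Prss34 (at least 20.6-fold) and histidine decarboxylase, Hdc (3.32 ± 0.16). Of 10 haematopoietic progenitor genes 5 rose (median 0.48, adjusted p = 0.042), including Gata2 (2.09 ± 0.15) and Kit (0.82 ± 0.10). The call ended with an estimated correlation (adjusted p = 0.101), with the block (adjusted p = 0.10) and without 1 of 3 arrays (control 6 wk replicate 1, 0.058; infected 6 wk replicate 2, 0.052; control 12 wk replicate 1, 0.051). It also ended with median scaling (0.052), cyclic loess (0.055) and stricter detection (0.052). Cell cycle genes rose in 28 of 30 (median 2.25, adjusted p = 1.78e-17), with Cdk1 at 3.18 ± 0.13 and Plk1 at 2.29 ± 0.12.

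Host defence lists at 6 weeks moved as follows. IFN-gamma-inducible genes rose in 21 of 26, with 1 lower (median 1.58, adjusted p = 6.52e-10), for example Acod1 (at least 8.67-fold), Fcgr1 (at least 8.33-fold) and Ubd (3.27 ± 0.14). Cytokine and chemokine genes rose in 9 of 21, with 2 lower (median 0.53, adjusted p = 0.00165), with the chemokines Ccl4 at 1.25 ± 0.13 and Ccl8 at least 6.47-fold higher. Pattern recognition genes rose in 10 of 23, with 2 lower (median 0.20, adjusted p = 0.0067, adjusted p = 0.0825 with an estimated correlation). Clec4n rose by 2.08 ± 0.10, whereas the DNA sensor adaptor Sting1 fell by 1.00 ± 0.11. Complement genes rose in 6 of 10 (median 0.80, or 0.77 with undetected members at their limit, adjusted p = 0.00421, adjusted p = 0.224 with an estimated correlation), led by C6 (4.10 ± 0.13). C6 in controls was 7.04 at 6 weeks against 10.30 and 8.47 at 3 and 12 weeks. The type I interferon list was not called (median 0.15, adjusted p = 0.0535), except in some alternatives, such as against the controls of the other weeks (median 0.33, adjusted p = 0.0084).

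B cell genes fell in 20 of 21 at 6 weeks (median -2.21, adjusted p = 1.61e-12), with Fcrla and Fcmr each at -2.21 ± 0.11 and Blk at -2.36 ± 0.12. T cell genes fell in 14 of 15 (median -1.91, adjusted p = 1.01e-08), including Cd8b1 (-2.28 ± 0.11), Cd3e (-1.94 ± 0.11) and Trat1 (-1.67 ± 0.12). Of 10 naive T cell genes 7 fell (median -1.76, adjusted p = 0.000591, adjusted p = 0.0765 with an estimated correlation), such as Satb1 (-2.12 ± 0.12) and Lef1 (at least 3.46-fold lower). NK cell genes fell in 8 of 11, with 1 higher (median -0.998, or -0.78 with undetected members at their limit, adjusted p = 0.0326), among them Klra7 (-2.25 ± 0.14) and perforin, Prf1 (-1.72 ± 0.20). The NK call was lost with an estimated correlation (adjusted p = 0.0948), with the block (adjusted p = 0.0943), and without control 6 wk replicate 2 (0.059) or infected 6 wk replicate 1 (0.068), and with stricter detection (0.052). Adjusted over the list alone, the counts at 6 weeks changed to 15 higher for monocytes, 1 lower for complement, 1 lower for progenitors, 29 higher for the cell cycle and 21 lower for B cells, and the others given were as above.

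At 6 weeks 4562 genes (40%) were called, 2101 higher and 2461 lower, with 1254 up and 1020 down by 2-fold or more. Under cyclic loess 2495 were higher and 2003 lower. With the array number as a block 7081 were called. Of the lists, 18 were called (14 up, 4 down), 13 of them also with an estimated correlation. Against the controls of the other weeks, a comparison added after seeing the data, the medians of the erythroid (3.31), megakaryocyte (2.43), red pulp (0.90) and granuloma lists (0.64) were smaller, and the adipose list (-0.92, or -0.64 with undetected members at their limit, adjusted p = 0.0064; -0.135, adjusted p = 0.613 in the chosen fit) was called. Genes already called rose less there, among them S100a8 (18.4-fold), Hemgn (4.56), Ltf (4.45), S100a9 (3.99), Hp (3.97), Camp (3.82), Car1 (3.66), Trim10 (3.37) and Nfe2 (3.33). So did Alas2 (2.39), Mrc1 (2.18), C6 (1.75), Treml4 (1.65), Cd14 (1.54), Slc11a1 (1.53), Gata2 (1.34), Slc40a1 (0.92) and Clec4n (0.83). Lcn2, Apol11b and Ngp, which were also lower in the 6-week than in the other controls, rose less there too. The pattern recognition median moved to 0.35 under cyclic loess, 0.72 with stricter detection, 0.47 without control 6 wk replicate 2, and 0.52 and 0.32 without infected 6 wk replicate 1 or 2. The cytokine median moved to 1.20 with stricter detection. Without the probe filter the medians were 0.23 for basophil, 0.18 for complement, 0.21 for granuloma, 0.30 for cytokine, 1.52 for mature neutrophil, 0.11 for progenitor and -0.46 for NK genes.

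**Figure D2:**
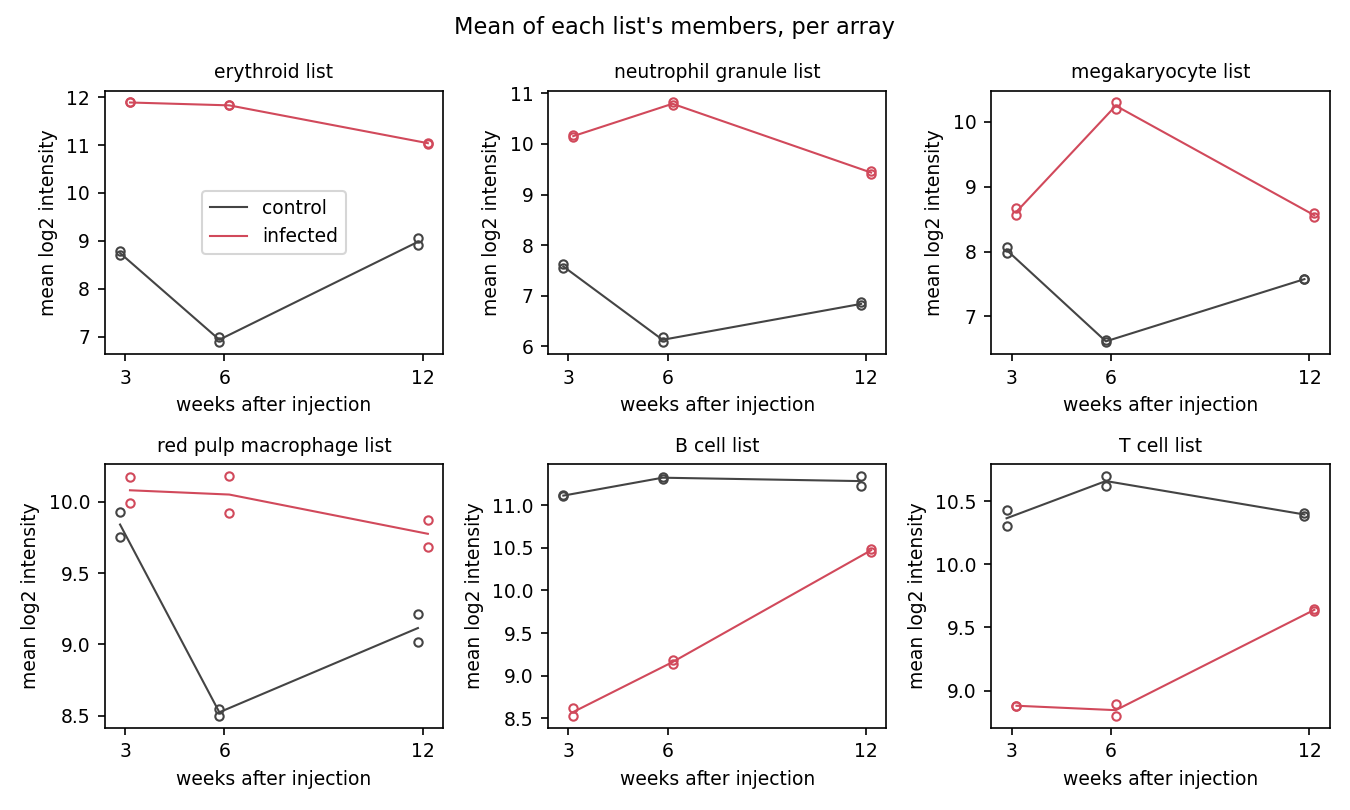
Mean normalized log2 intensity of the members of 6 gene lists on each array (open points), by weeks after injection, for control (grey) and infected (red) spleens, with lines through the group means. Erythroid genes lie lowest in the 6-week controls, and B and T cell genes lie lower in infected than in control spleens at every week.

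The comparison at 12 weeks asks which differences were present late. Transcripts of Saa3 and of neutrophil and interferon-inducible genes were higher in infected spleens, those of B and T cells were lower, and transcripts of liver and fat were lower. Saa3 was 57.0-fold higher (log2 change 5.83 ± 0.19, limma adjusted p = 1.7e-06) and Gbp2b 29.7-fold higher (4.89 ± 0.51). The neutrophil genes Lcn2, S100a8 and S100a9 were 25.6-fold, 25.2-fold and 19.2-fold higher, Chil3 19.4-fold, Ngp 16-fold and the formyl peptide receptor Fpr2 15.6-fold, with Retnlg at least 20.5-fold and Ctsg at least 14.5-fold higher. Cd209b was 9.17-fold lower (-3.20 ± 0.23), and Siglech, a receptor of plasmacytoid dendritic cells, was 6.31-fold lower (-2.66 ± 0.34).

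Of the 10 largest falls at 12 weeks, 6 were in genes that the liver expresses in abundance, namely Cyp2e1 (at least 6.15-fold lower), the major urinary protein Mup2 (-2.98 ± 0.21), the apolipoproteins Apoa2 (-2.74) and Apoa1 (-2.63), the fibrinogen chain Fga (-2.43) and Ambp (-2.37). Adipoq was at least 4.92-fold lower (-2.57 ± 0.11) and the kallikrein Klk1b5 at least 3.48-fold lower. Of 40 liver genes listed after the data were seen, 24 were measured, and 20 of them were lower and 0 higher in infected spleens at 12 weeks (median -1.91, or -1.73 with undetected groups at their limit). The mean of these 24 genes was 8.06 on both 12-week control arrays and 6.35 and 6.38 on the infected arrays of that week. All 24 lay higher in the 12-week controls than the mean of the 3-week and 6-week controls (median 2.30, or 1.70 with undetected groups at their limit), though Trf was lower at 12 weeks (11.11) than in the 3-week controls (11.75). These counts are no independent support, since the list was made after the data were seen and holds the 6 genes above. The detection filter also favoured genes high in the 12-week controls. On those arrays 23 and 24 of the 24 were detected, against 6 to 9 on the other control arrays. Only 5 of the 24 were above the lowest detected signal in the controls of both 3 and 6 weeks, so the others could hardly lie lower in infected spleens (18 of 24 higher, median 0.44, or 0.22 at the limit). Of these 5, Serpina1b (-0.54), Serpina1c (-0.36) and Serpina1d (-0.38) lay lower in 12-week infected spleens than in those controls. Apoc1 (0.65) and Trf (0.50) lay higher. Serpina1b, Serpina1c and Serpina1d, counted among the 20, also lay lower in infected than in control spleens at 3 and 6 weeks. Mup2, Ambp, Apoa2, Apoa1 and Fga were not detected in the controls of the other weeks. Compared with these, they were at least 4.31-fold, 1.71-fold, 1.57-fold, 1.44-fold and 1.20-fold higher in infected spleens, and Cyp2e1 was no longer called (adjusted p = 0.14).

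IFN-gamma-inducible genes rose in 16 of 26 at 12 weeks and fell in 0 (18 higher and 1 lower adjusted over the list alone; median 1.10, adjusted p = 2.99e-11), with Ubd at 3.11 ± 0.14, Acod1 at least 3.09-fold higher and Cxcl9 at 1.60 ± 0.10. Type I interferon genes rose in 9 of 26 (median 0.45, adjusted p = 0.00495), led by Isg15 (2.44 ± 0.20) and Rsad2 (2.02 ± 0.12). The list was not called against the controls of the other weeks (adjusted p = 0.063). Cytokine genes rose in 8 of 21 (median 0.40, or 0.35 with undetected members at their limit, adjusted p = 4.12e-05), including Ccl8 (at least 5.59-fold), Ccl4 (1.54 ± 0.13) and Il15 (1.01 ± 0.10). Pattern recognition genes rose in 10 of 23, with 1 lower (median 0.49, adjusted p = 4.59e-05), such as Clec4n (1.58 ± 0.10) and Cd14 (1.70 ± 0.12). Complement genes rose in 6 of 10 (median 0.51, or 0.48 with undetected members at their limit, adjusted p = 0.000858, adjusted p = 0.162 with an estimated correlation). C6 rose by 2.62 ± 0.13 and C1qa by 1.77 ± 0.18. Of 18 MHC class I and immunoproteasome genes 3 rose (median 0.29, adjusted p = 0.0187, adjusted p = 0.157 with an estimated correlation), namely H2-Q6 (0.77 ± 0.17), Psmb10 (0.49 ± 0.12) and H2-M3 (0.45 ± 0.12), though the call was lost without infected 12 wk replicate 1 (0.054). Each of these 3 genes lost its call when single 12-week arrays were left out, with adjusted p up to 0.09 for H2-Q6, 0.13 for Psmb10 and 0.14 for H2-M3, and with the arrays of the week alone (0.073, 0.17 and 0.18).

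Myeloid lists at 12 weeks stayed above control. Neutrophil granule genes rose in 17 of 19, with 1 lower (median 2.93, adjusted p = 8.15e-18), with Camp at 3.86 ± 0.11 and Mpo at 3.47 ± 0.12, and mature neutrophil genes in 10 of 15, with 1 lower (median 1.30, adjusted p = 4.84e-07). Monocyte genes rose in 9 of 19, with 2 lower (median 1.16, adjusted p = 1.57e-05), including Fcgr4 (2.94 ± 0.13). Red pulp and marginal zone genes rose in 9 of 18, with 3 lower (median 1.16, adjusted p = 0.000231), with Mrc1 (2.56 ± 0.13) and Spic (1.70 ± 0.11) against the fall of Cd209b. Granuloma genes rose in 7 of 14 (median 0.62, adjusted p = 0.000374), among them Mmp13 (at least 4.39-fold) and Gpnmb (1.82 ± 0.11). Basophil, eosinophil and mast cell genes rose in 5 of 9 (median 1.14, or 0.79 with undetected members at their limit, adjusted p = 0.00012, adjusted p = 0.051 with an estimated correlation). They included the eosinophil granule protein Prg2 (2.63 ± 0.15) and Prss34 (2.83 ± 0.21). Erythroid genes rose in 21 of 24 (median 2.22, or 2.15 with undetected members at their limit, adjusted p = 1.45e-22), with Car1 at 2.98 ± 0.13 and Car2 at 2.83 ± 0.14, and megakaryocyte genes in 10 of 15 (median 0.88, adjusted p = 4.79e-07), with Gp9 at 1.39 ± 0.19. Cell cycle genes rose in 22 of 30 (median 1.22, adjusted p = 1.07e-17), with Birc5 at 2.03 ± 0.13 and Cdk1 at 1.91 ± 0.13.

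B cell genes fell in 16 of 21 at 12 weeks (median -0.79, adjusted p = 1.85e-09), for example Ralgps2 (-1.13 ± 0.12) and Fcmr (-0.85 ± 0.11), and T cell genes in 12 of 15 (median -0.75, adjusted p = 9.14e-07), for example Cd3e (-0.86 ± 0.11) and the co-stimulatory receptor Cd28 (-1.52 ± 0.25). Of 10 naive T cell genes 4 fell (median -0.65, adjusted p = 0.00665, adjusted p = 0.141 with an estimated correlation). Satb1 fell by 1.00 ± 0.12. Of 6 adipose genes 3 fell (median -0.76, or -0.53 with undetected members at their limit, adjusted p = 0.000231), namely Adipoq, the lipid droplet protein Plin4 (at least 3.03-fold lower) and Cidec (at least 1.07-fold lower). Adipoq lay at 7.80 and 7.77 on the 12-week control arrays and at 5.07 and 5.05 on the 6-week control arrays, and against the controls of the other weeks the adipose list (median -0.29, adjusted p = 0.11), Plin4 (0.12) and Cidec (0.21) were not called. Adjusted over the list alone, the counts at 12 weeks changed to 1 lower for type I interferon, 11 higher for pattern recognition, 2 lower for mature neutrophils, 11 higher for monocytes, 10 higher for red pulp, 8 higher and 1 lower for granuloma, 22 higher for erythroid, 12 higher for megakaryocyte, 25 higher for cell cycle, 18 lower for B cell and 5 lower for naive T cell genes.

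At 12 weeks 2315 genes (20.3%) were called, 1199 higher and 1116 lower, with 609 up and 246 down by 2-fold or more, and 19 lists (15 up, 4 down), 15 of them also with an estimated correlation. With the array number as a block 5154 genes were called, including H2-Q7 (0.28 ± 0.11, adjusted p = 0.016 against 0.11), with 2322 higher and 2832 lower, and with the 4 arrays of the week alone 781 (551 higher, 230 lower). Median scaling gave 1133 higher and 1149 lower. Leaving out control 12 wk replicate 1, infected 12 wk replicate 1 or infected 12 wk replicate 2 gave 1472, 1502 and 1377, and without the first of these the medians of the monocyte and adipose lists were 0.63 and -0.50. The medians of the erythroid (3.64) and granuloma lists (0.99, or 0.66 with undetected members at their limit) were larger against the controls of the other weeks, as was the rise of Rsad2 (3.14), and the rise of Ccl4 (0.99) and the fall of Adipoq (at least 1.80-fold) were smaller, and the NK list was called (median -0.89, or -0.62 at the limit, adjusted p = 0.013; -0.446, adjusted p = 0.233 in the chosen fit). Without the probe filter the medians were 0.08 for basophil, 0.09 for complement, 0.10 for granuloma, 0.62 for mature neutrophil, 0.73 for monocyte and -0.33 for adipose genes.

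**Figure D3:**
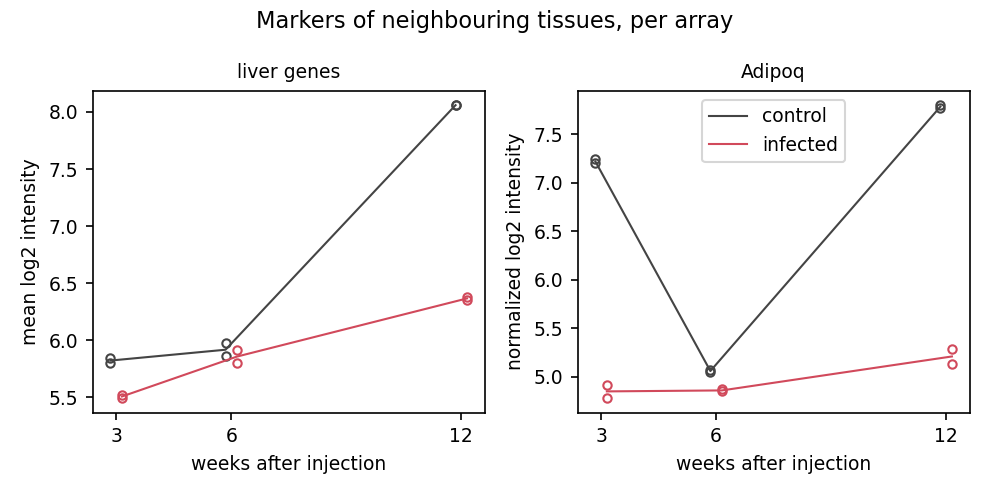
Mean log2 intensity of 24 liver genes (left) and normalized log2 intensity of Adipoq (right) on each array (open points), by weeks after injection, with lines through the group means of control (grey) and infected (red) spleens. The liver genes reach 8.06 on both 12-week control arrays, and Adipoq lies above 7 on the 3-week and 12-week control arrays alone.

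The fixed host defence genes kept the following course. Ifng, interferon gamma, rose by 2.93 ± 0.23, 2.82 ± 0.23 and 2.13 ± 0.23 at 3, 6 and 12 weeks (limma adjusted p = 2.1e-05, 2.2e-05 and 0.0004). Gbp2 rose by 2.38, 1.76 and 1.10, and Slc11a1 by 1.48, 2.35 and 1.34. Irgm1, an interferon-inducible GTPase, rose by 1.22 ± 0.17 and 0.79 ± 0.17 at 3 and 6 weeks and was not called at 12 weeks (0.36, adjusted p = 0.19; 0.027 without control 12 wk replicate 2). Tnf rose at 3 weeks (1.11 ± 0.22, adjusted p = 0.0044) and was not called at 6 and 12 weeks (-0.14 and -0.06, adjusted p = 0.68 and 0.90). Il10 rose by 1.24 and 0.95 at 3 and 6 weeks and at least 1.97-fold at 12 weeks (adjusted p = 0.0055, and 0.051 with the arrays of that week alone). At 6 weeks its call was lost without control 6 wk replicate 2 (adjusted p = 0.065) or infected 6 wk replicate 1 (0.054). Il4, the type 2 cytokine, fell at 3 weeks (-0.96 ± 0.27, adjusted p = 0.023), though not without control 3 wk replicate 1 or infected 3 wk replicate 2 (adjusted p = 0.15 each) or with the arrays of that week alone (0.076). It was not called at 6 or 12 weeks (-0.42 and -0.06). Nos2 passed the test at 6 weeks only narrowly (0.44 ± 0.15, adjusted p = 0.046), with a limit of 1.01-fold, and was not called in most alternatives, such as without background correction (adjusted p = 0.17), with median scaling (0.066), or without any 1 array of that week (0.08 to 0.19). At 12 weeks it was detected in neither group. Foxp3, the regulator of regulatory T cells, was not called at any week (-0.18, -0.09 and -0.05). Il12b, Il6, Il17a and Ighg2c were not measured.

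**Figure D4:**
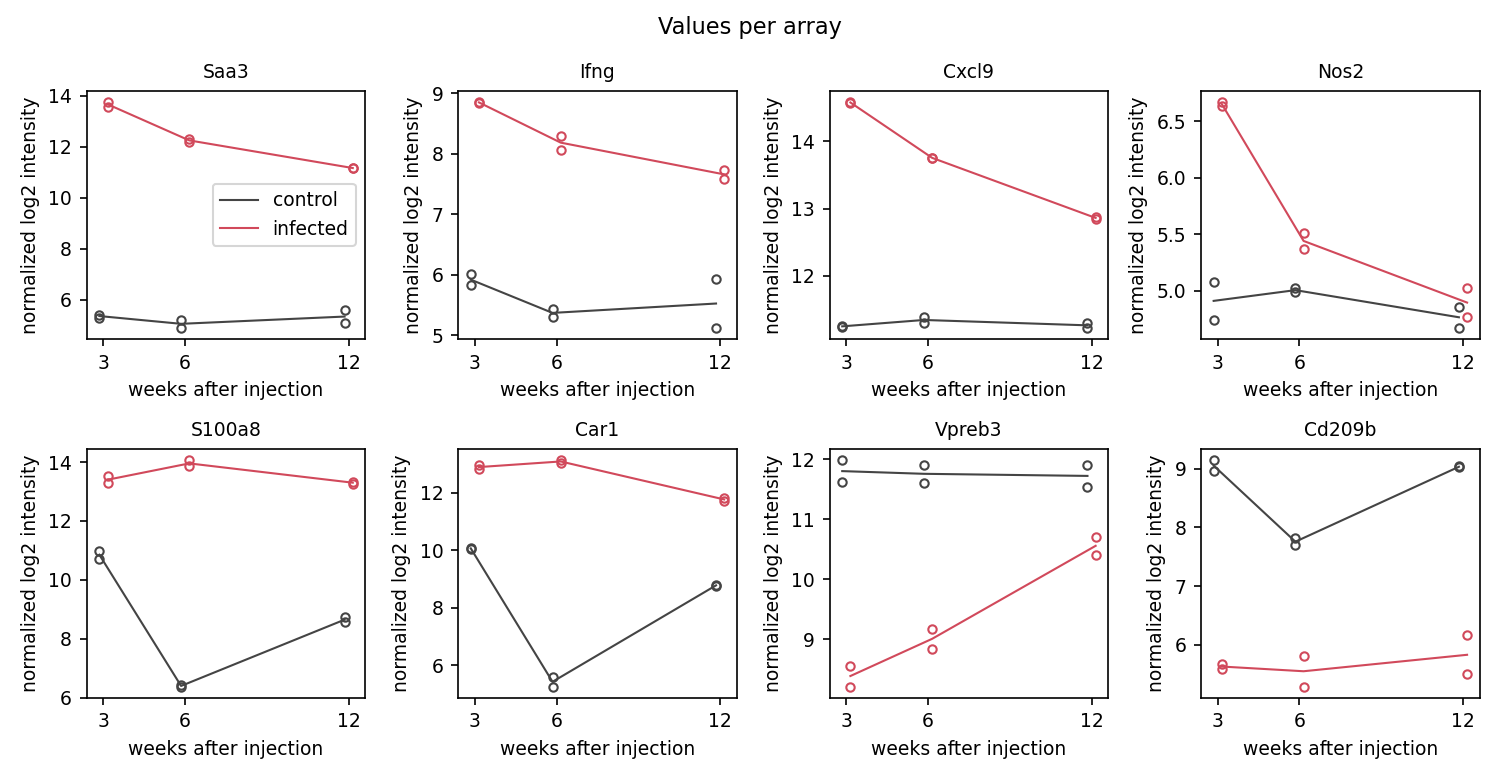
Normalized log2 intensity of Saa3, Ifng, Cxcl9, Nos2, S100a8, Car1, Vpreb3 and Cd209b on each array (open points), by weeks after injection, with lines through the group means of control (grey) and infected (red) spleens. Saa3 lies at 13.67, 12.26 and 11.17 in infected spleens and near 5 in controls, and S100a8 and Car1 dip in the 6-week controls.

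Averaged over the weeks, infected spleens held more transcripts of Saa3 (at least 127-fold; 7.12 ± 0.11, limma adjusted p = 2.5e-09), Apol11b (46.6-fold), Gbp2b (44.4-fold), Lcn2 (at least 41.1-fold), Hemgn (33.5-fold) and S100a8 (30.2-fold). Ngp, Retnlg, Rhag and Chil3 were at least 27.2-fold, 25.4-fold, 24.8-fold and 23.1-fold higher. Cd209b was 7.67-fold lower (-2.94 ± 0.13) and Siglech 6.23-fold lower (-2.64 ± 0.20). Fcer2a was 5.65-fold, the endothelin receptor Ednrb 5.57-fold, Psmb1 5.56-fold, Vpreb3 5.44-fold and Cox6a2 5.28-fold lower, with Lrat at least 5.49-fold and Klk1b5 at least 4.36-fold lower. Nme7 was 5.10-fold lower by its brightest probe, but only 2 of its 5 other probes shared that sign. Erythroid and cell cycle genes rose in all 24 and all 30 measured members (medians 3.73 and 1.82, camera adjusted p = 1.75e-19 and 2.73e-17), and B cell genes fell in all 21 (median -1.92, adjusted p = 6.24e-12). Tnf was not called on average (0.30 ± 0.13, adjusted p = 0.079), but it was with the array number as a block (adjusted p = 0.0011), under cyclic loess (0.42, adjusted p = 0.015), without control 6 wk replicate 1 (0.043), without control 12 wk replicate 1 (0.045) and, added after seeing the data, without the 6-week arrays (0.53, adjusted p = 0.026) and without the 12-week arrays (0.49, adjusted p = 0.033).

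The remaining lists called on average were IFN-gamma-inducible (24 of 26 higher, 1 lower, median 1.37, adjusted p = 6.24e-12), type I interferon (12 of 26 higher, 2 lower, 0.34, 0.00415), cytokines (12 of 21 higher, 2 lower, 0.68, 0.000207), pattern recognition (13 of 23 higher, 2 lower, 0.35, 0.000302) and monocyte genes (16 of 19 higher, 2 lower, 1.21, 1.5e-06). Red pulp (11 of 18 higher, 3 lower, median 1.23, adjusted p = 0.000302), granuloma (9 of 14 higher, 2 lower, 0.82, 0.000727), mature neutrophil (13 of 15 higher, 1 lower, 1.64, 2e-07), neutrophil granule (17 of 19 higher, 2 lower, 3.80, 1.81e-12) and megakaryocyte genes (14 of 15 higher, 1.83, 9.19e-09) rose, and T cell genes fell in 14 of 15 (-1.35, 8.21e-08). The calls of 5 further lists were lost with an estimated correlation. Complement genes rose in 6 of 10 (median 0.92, adjusted p = 0.00141, adjusted p = 0.171 with an estimated correlation), and basophil and mast cell genes in 7 of 9, with 1 lower (1.15, 0.000302, adjusted p = 0.0598 with an estimated correlation). Naive T cell genes fell in 8 of 10 (-1.57, 0.000346, adjusted p = 0.0598 with an estimated correlation). NK cell genes fell in 9 of 11, with 1 higher (-0.95, 0.00769, adjusted p = 0.0526 with an estimated correlation), and adipose genes in 4 of 6 (-0.58, 0.0165, adjusted p = 0.069 with an estimated correlation). Adjusted over the list alone, 14 pattern recognition and 8 basophil genes were higher, and 15 T cell and 9 naive T cell genes lower. In the block fit the MHC class I list (median 0.16, adjusted p = 0.0212) and the lysosome list (median 0.31, adjusted p = 0.0237) were called as well. Without the probe filter the MHC class I (adjusted p = 0.031), stromal (-0.41, adjusted p = 0.033) and oxidative burst lists (0.36, adjusted p = 0.031) were called and the adipose list was not (-0.11, adjusted p = 0.055), and the medians were 0.33 for basophil, 0.18 for complement, 0.34 for granuloma and 0.22 for type I interferon genes. The MHC class I list was also called under cyclic loess (0.27, adjusted p = 0.018), and the pattern recognition median was 0.62 with stricter detection.

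The average called 5848 genes (51.2%), 2555 higher and 3293 lower, 961 and 661 of them by 2-fold or more. Under cyclic loess 2981 were higher and 2739 lower. Without the 6-week arrays 4141 were called and without the 12-week arrays 5558, and with both arrays of a group averaged first and the weeks as 3 pairs 2913 were called, alternatives added after seeing the data. At single weeks 5660 genes were called at least at 1 week, 879 were higher and 769 lower at all 3, and 99 were called in opposite directions at different weeks. Genes higher at both 3 and 6 weeks numbered 1524 (353 if the calls were independent) and genes lower at both 1763 (492). For 3 and 12 weeks the shared counts were 902 (201) and 814 (223), and for 6 and 12 weeks 1067 (221) and 893 (241), each week having its own controls. Across genes, which are not independent replicates, the log2 changes correlated at 0.857 between 3 and 6 weeks, 0.720 between 3 and 12, and 0.829 between 6 and 12. The median change of all genes was -0.079, -0.089 and -0.041 at 3, 6 and 12 weeks. It moved to -0.184 at 3 weeks with median scaling and to 0.015 at 6 weeks with cyclic loess, so changes of that size carry no direction here.

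Whether infection acted differently at the 3 weeks was tested on the effects themselves. The gene with the smallest p was Clec4g, a C-type lectin of sinusoidal endothelium, which was lower in infected spleens at 3 weeks (-2.53 ± 0.10) and higher at 6 and 12 weeks (2.40 ± 0.10 and 1.40 ± 0.10; F-test adjusted p = 7.2e-06). The erythroid genes Trim10, Car1, Alas2 and Nfe2 exceeded the controls of the same week most at 6 weeks. For Trim10 the effects over the weeks were 3.59, 7.44 and 2.25. The neutrophil genes Camp (2.40, 6.68 and 3.86) and S100a8 (2.55, 7.55 and 4.65) also had their largest effect at 6 weeks. So had F2rl2 (1.01, 4.66 and 0.87, the last not called with the arrays of that week alone). Itgad, an integrin of red pulp macrophages, differed by 0.20 (limma adjusted p = 0.20), then by 4.07 and 2.41. Ank1, the ankyrin of the red cell membrane, rose by 4.60, 6.20 and 1.63. In the controls Clec4g lay at 12.06, 9.01 and 10.37 and Itgad at 11.10, 7.87 and 9.46.

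From 3 to 6 weeks the effect on 15 lists differed (13 up, 2 down), most for megakaryocyte (difference 3.10, camera adjusted p = 4.37e-27), neutrophil granule (2.05, 3.37e-24) and erythroid genes (1.83, 5.22e-25). The rise of IFN-gamma-inducible genes was smaller at 6 weeks (-0.53, 4.58e-05). From 6 to 12 weeks 19 lists differed (8 up, 11 down), with smaller rises of erythroid (-3.19, 2.5e-28), megakaryocyte (-2.88, 4.4e-17), neutrophil granule (-2.23, 2.55e-17) and cell cycle genes (-0.95, 4.79e-13) and smaller falls of B cell (1.39, 9.68e-16) and T cell genes (1.08, 4.45e-09). From 3 to 12 weeks 12 lists differed (9 up, 3 down), including B cell (1.71, 1.82e-17), IFN-gamma-inducible (-0.88, 5.21e-08) and erythroid genes (-1.18, 3.1e-11). Set against the other weeks, the 6-week controls differed more than the infected spleens in erythroid (medians -2.19 and 0.38) and red pulp genes (-0.84 and 0.17), and less than them in megakaryocyte (-1.29 and 1.79) and granule genes (-0.84 and 1.17).

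The F-test called 1573 genes (13.8%). Pairwise, 445 genes differed between 3 and 6 weeks (358 with a higher effect at 6 weeks, 87 lower), 1430 between 3 and 12 (755 and 675) and 1180 between 6 and 12 (498 and 682). With the block 5167 genes passed the F-test and 1971, 4408 and 3879 the pairwise tests, and 892 differed between 3 and 12 weeks when the 6-week arrays were left out. Without control 12 wk replicate 1, infected 12 wk replicate 1 or infected 12 wk replicate 2 the F-test called 1040, 969 and 989.

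The control groups were compared with each other to give the differences between sampling times without infection. Each time had a single control group, so time cannot be told apart from dissection, batch or the mice themselves. The genes with the smallest p were erythroid and neutrophil genes that were lowest at 6 weeks and liver genes that were highest at 12 weeks. Trim10 lay at 10.55, 6.55 and 10.71 in the controls of 3, 6 and 12 weeks (F-test adjusted p = 2.7e-06), Alas2 at 12.19, 9.06 and 12.16 and Camp at 9.75, 6.32 and 8.60, with Car1, S100a8, Itgad and Clec4g as given above. Mup2 lay at 10.50, Ambp at 8.56 and Kng1, the kininogen of liver and plasma, at 8.72 in the 12-week controls. Mup2 and Ambp were not detected in the controls of 3 and 6 weeks, and Kng1 was detected at 6 weeks (5.75) and not at 3. The F-test called 484 genes (4.2%). Between 3 and 6 weeks 425 differed, 381 of them lower at 6 weeks and 44 higher, and between 3 and 12 weeks 198 differed, 89 higher and 109 lower. With the block the F-test called 2125 and the pairs 1726 and 877, without control 6 wk replicate 1 or 2 it called 306 and 274, without control 3 wk replicate 1 310, and without the 6-week arrays 103.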

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

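The tests of the lists in single groups of arrays and of liver genes were chosen only after the result was seen. The test of lymph node genes was written before its values were seen, but the need for 5 genes above the lowest detected signal was added after, and without it -0.19 would have counted against that explanation.

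The results in this part were singled out because the effect of infection differed between weeks by a test of the difference itself. The F-test called 1573 genes. Among the 10 with the smallest p, the effect at 6 weeks exceeded that at 3 weeks by 4.93 in Clec4g, 3.85 in Trim10, 4.83 in Car1, 4.28 in Camp, 3.11 in Alas2, 1.59 in Ank1, 3.86 in Itgad, 2.78 in Nfe2, 3.65 in F2rl2 and 5.01 in S100a8.

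Among gene lists, the median effect at 6 weeks minus that at 3 weeks was 3.10 for megakaryocyte, 2.05 for neutrophil granule, 1.83 for erythroid, 1.31 for basophil and mast cell, 1.18 for red pulp, 0.72 for mature neutrophil and 0.72 for NK cell genes. It was 0.63 for adipose, 0.60 for progenitor, 0.39 for monocyte, 0.33 for B cell and -0.53 for IFN-gamma-inducible genes. Plasma cell genes differed by 0.53 (adjusted p = 0.0507 with an estimated correlation), T cell genes by -0.32 (adjusted p = 0.081 with an estimated correlation) and stromal genes by 0.33 (adjusted p = 0.382 with an estimated correlation). The monocyte difference moved when arrays were left out, to 0.00 without control 6 wk replicate 1 and 0.02 without control 3 wk replicate 2. It was 0.03 without infected 6 wk replicate 2 and 0.12 without infected 3 wk replicate 1. Without 1 of the other arrays of both weeks it was 0.62 to 0.78. In every group the monocyte list had a higher mean on array 2 than on array 1, such as 9.50 against 9.31 in the 3-week controls. These moves therefore also hold the shared difference by array number. The T cell difference was -0.20 and -0.54 without control 3 wk replicate 1 or 2 and -0.19 with median scaling, and that of NK cells 1.12 without control 6 wk replicate 2. Without the probe filter the differences were 0.62 for basophil, 0.45 for mature neutrophil, 0.26 for adipose, 0.24 for progenitor and 0.20 for monocyte genes.

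From 3 to 12 weeks the median effect differed by 1.71 for B cell, 1.15 for NK cell, -0.88 for IFN-gamma-inducible, -1.18 for erythroid and -0.79 for cell cycle genes. Differences that were lost with an estimated correlation were those of T cell (0.60, adjusted p = 0.05), naive T cell (0.79, adjusted p = 0.132), germinal centre B cell (0.56, adjusted p = 0.132), plasma cell (0.49, adjusted p = 0.177), dendritic cell (0.42, adjusted p = 0.132), MHC class II (0.18, adjusted p = 0.132) and stromal genes (0.43, adjusted p = 0.325), each p with that correlation. The array block ended those of MHC class II (adjusted p = 0.053), germinal centre (0.073) and dendritic cell genes (0.079). Germinal centre genes also lost the call with median scaling, stricter detection, no probe filter and without control 3 wk replicate 2 (0.052 to 0.06), dendritic cell genes with median scaling (0.067) and without any 1 of 4 arrays (0.081 to 0.14), and MHC class II genes under cyclic loess (0.076). The MHC class II difference was 0.27 and 0.11 without control 3 wk replicate 1 or 2, and without the probe filter those of NK and dendritic cells were 0.53 and 0.22.

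From 6 to 12 weeks it differed by -3.19 for erythroid, -2.88 for megakaryocyte, -2.23 for neutrophil granule, -1.23 for mature neutrophil, -0.93 for red pulp, -0.62 for monocyte, -0.95 for cell cycle, -0.46 for IFN-gamma-inducible and -0.71 for adipose genes. It rose by 1.39 for B cell, 1.08 for T cell, 0.74 for NK cell, 0.74 for Th1 and cytotoxic and 0.34 for MHC class II genes. Lost with an estimated correlation were the differences of naive T cell (0.89, adjusted p = 0.0713), germinal centre B cell (0.49, adjusted p = 0.104), regulatory T cell (0.23, adjusted p = 0.104), basophil (-0.80, adjusted p = 0.149) and complement genes (-0.29, adjusted p = 0.366), each p with that correlation. The array block ended those of regulatory T cell (adjusted p = 0.085), germinal centre (0.097) and complement genes (0.062), as did median scaling (0.066, 0.057 and 0.067) and leaving out several single arrays (0.059 to 0.099). The basophil call was lost without infected 6 wk replicate 1 or 2 (0.078 and 0.054). The Th1 and cytotoxic difference fell to 0.43 without infected 6 wk replicate 1, 0.49 without infected 12 wk replicate 2 and 0.36 without background correction, and that of adipose genes to -0.46 without control 12 wk replicate 1. Without the probe filter the differences were -0.20 for basophil, 0.10 for germinal centre (not called, adjusted p = 0.059), 0.37 for NK, -0.40 for adipose and -0.17 for complement genes.

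The larger 6-week effects of erythroid, granule, megakaryocyte and red pulp genes may rest on the controls, on the infected spleens or on both. For erythroid and red pulp genes the 6-week controls lay lower than the other controls (medians -2.19 and -0.84) while infected spleens differed by 0.38 and 0.17, which argues against a peak in infected spleens as the main source. For megakaryocyte and granule genes infected spleens lay higher (1.79 and 1.17) and controls lower (-1.29 and -0.84). Both thus carry part of the larger 6-week effect, which exceeded the mean of the other effects by medians of 3.08 and 2.24. Lymph node tissue in place of part of the spleen in the 6-week controls stays open. The 6 measured lymph node vessel genes lay at a median of -0.19 from the other controls. Only 3 were above the lowest detected signal in all controls, too few to exclude it. The listed red pulp genes, from Nkx2-3 (-0.20) to Itgad (-2.41), all lay lower. Many of them belong to the lists whose low values in these controls were to be explained, so they are no separate support. White pulp and marginal zone genes went both ways, from Cd209b (-1.29) to Cr2 (0.58). A difference in perfusion, dissection or batch of the 6-week control mice, or in the mice themselves, was not tested.

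The lower liver transcripts in infected spleens at 12 weeks may come from liver RNA in the control samples of that week. The 24 measured liver genes lay a median of 2.30 higher in these controls than the mean of the other controls, or 1.70 with undetected groups at their limit, with Mup2 at 10.50 and Ambp at 8.56. The later choice of the list and the detection filter both favoured genes high in these controls, so that median is no independent support. A fall in infected spleens below the level of the other controls stays open, because most of these genes were near the limit of detection there and could not lie lower. The 5 above it, Apoc1, Trf, Serpina1b, Serpina1c and Serpina1d, had a median of -0.36 in 12-week infected spleens, 2 higher and 3 lower, which decides nothing. A rise with age in control spleens that infection prevented stays open as well, as untested.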

How the results depend on the processing

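The comparisons with the controls of other weeks, without all arrays of a week, and with group means as pairs were added after seeing the data. Of 387 gene results, at least 384 kept direction and side of the threshold under all probes, array weights, cyclic loess, stricter detection (384 of 384 measured), median scaling, no background correction, no probe filter, a larger offset, a trended prior and the array block, and 366 with the arrays of a week alone. Most of these genes were named for large changes or small p in the chosen fit, so this says little about other genes. With group means as pairs, which do not count the arrays of a group as replicates, 88 of 99 results stayed and 11 lost their call. Of 231 list results, 197 did so with an estimated correlation, 159 with fry and 217 with the block; besides the changes given beside the results, the block called Cidec at 3 weeks (adjusted p = 0.041) and ended the calls of MHC class II, germinal centre B and dendritic genes for 12 minus 3 weeks and of regulatory T, complement and germinal centre B genes for 12 minus 6 weeks, and no others.

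For the weeks in control spleens (484), median scaling gave 1258, all probes 759, the block 2125 and the 3-week and 12-week controls alone 103. All probes as units, which tests more features, gave 6477, 7164 and 9407 at 3 weeks, 6 weeks and on average. The authors' normalized table, in which every probe was tested without names because its identifiers do not go with its values, gave 10798, 11641, 7545 and 13598 for 3, 6 and 12 weeks and the average, 7809 for the difference between weeks and 3762 for control spleens; lists and named genes were not run on it. The block gave 6718, 7081, 5154 and 5167 for 3, 6 and 12 weeks and the difference between weeks. At 12 weeks the arrays of the week alone, with fewer samples, gave 781, and the controls of other weeks 3474. The difference between weeks without the 6-week arrays gave 892, and group means as pairs, with 2 residual degrees of freedom, 2913 on average. Except where more features or fewer samples show it, the cause was not tested.

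Leaving out 1 array at a time, with the lone array assumed to vary like the other groups, gave 3138 to 4161, 3557 to 4559 and 1377 to 2126 genes at 3, 6 and 12 weeks, 5355 to 5587 on average, 969 to 1159 for the difference between weeks and 274 to 424 in control spleens. Lists called numbered 19 to 21, 17 to 19, 18 to 19 and 19 on average, and 15, 10 to 13 and 15 to 19 for 6 minus 3, 12 minus 3 and 12 minus 6 weeks. With fry, which tests a list without other genes for comparison, 31, 30 and 33 lists were called at 3 and 6 weeks and on average, and 26 for 12 minus 3 weeks, where the estimated correlation left 5.

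Fry turned the direction of plasma cell (median 0.37) and pancreas genes (-0.55) at 6 weeks, oxidative burst genes from 3 to 6 weeks (-0.23) and mature neutrophil genes from 3 to 12 weeks (-0.11). Against the controls of other weeks, Cxcl12 at 3 weeks (0.33) and Mup2 (2.49), Apoa2 (1.05), Apoa1 (0.87), Fga (0.72) and Ambp (1.36) at 12 weeks reversed. The last 5 were not detected in those controls, and with them at their limit were 2.11, 0.65, 0.53, 0.27 and 0.77. Values themselves shrank without background correction and with the larger offset, for example Acod1, infection at 3 weeks, from 5.42 to 3.52 without background correction and Ccl8, infection at 3 weeks, from 3.44 to 2.24 with the larger offset, and without the probe filter the median of complement, infection at 6 weeks, was 0.18 against 0.80. A block for the slide was not run, since no slide information was used. Signal over background limits what was tested: 37.77% to 40.56% of probes were detected per array, and folds against undetected groups are lower limits.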

Other observations

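The tests of the array number and of 1 RNA on both arrays were chosen only after the result was seen, and the test of other splits was written before.

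Several cell types and functions gave lists that camera did not call at any week in the chosen fit. Regulatory T cell and inhibitory receptor genes had medians of -0.25, -0.17 and -0.07 at 3, 6 and 12 weeks (adjusted p = 0.278, 0.293 and 0.869), with 3, 2 and 3 of 15 genes higher and 6, 6 and 1 lower. Th1 and cytotoxic effector genes had medians of -0.19, -0.35 and 0.19 (adjusted p = 0.515, 0.359 and 0.236), while Ifng itself rose at every week. Dendritic cell genes had medians of -0.44, -0.51 and -0.24 (adjusted p = 0.132, 0.359 and 0.869). Of 16 MHC class II genes 6, 5 and 1 fell and 1, 0 and 2 rose, and their median and mean parted at 3 weeks (0.003 and -0.457, adjusted p = 0.133). Germinal centre B cell genes (median -0.35 at 3 weeks, adjusted p = 0.132) and plasma cell genes (-0.37, adjusted p = 0.0769) passed at no week either. In single alternatives some passed: plasma cell genes at 3 weeks with stricter detection (-0.52, adjusted p = 0.044), and MHC class II genes at 6 weeks without the probe filter (adjusted p = 0.02) and with a trended prior (0.049). Lysosome genes (0.26, 0.45 and 0.13) and cholesterol genes (0.37, 0.24 and -0.004) were likewise not called, nor were immediate early (0.12, 0.36 and -0.15) or pancreas genes (-0.13, -0.55 and 0.43). The means of the pancreas list had the other sign at 3 and 6 weeks (0.101 and 0.304), as had that of the cholesterol list at 12 weeks (0.202). Against the controls of the other weeks, added after seeing the data, lysosome (0.45, adjusted p = 0.037) and cholesterol genes (0.26, adjusted p = 0.049) at 3 weeks and pancreas genes at 12 weeks (0.40, or 0.22 with undetected members at their limit, adjusted p = 0.038) were called, and with the array block lysosome genes at 3 weeks (0.26, adjusted p = 0.027). Fry, which tests a list without other genes for comparison, called many of these lists.

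Array numbers 1 and 2 may stand for a technical step shared by the 6 groups, since the lowest correlation of the difference between both arrays across groups was 0.66. Both arrays of a group may also hold 1 RNA sample. The liver genes differed by at most 0.11 between them against a range of 2.56 between groups. On the arrays of 3 and 6 weeks only 5 to 13 of the 24 liver genes were detected, so those groups decide little. At 12 weeks, with 16 to 24 detected, both arrays lay at 8.06 in controls and at 6.35 and 6.38 in infected spleens. If both arrays of a group held 1 RNA, the p values above measure the spread between arrays and not between mice. Differences between groups of mice could then be read as effects of infection or week. Pools of the same mice on both arrays stay open as well.

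For infection averaged over the weeks, 100 of 108 splits that exchange labels within weeks were drawn, the real one included. The real split gave 5848 genes and the highest other 4137, so chance can be excluded only if the arrays are separate samples. If both arrays of a group hold 1 RNA, which the difference of 0.11 above leaves open, only 4 splits keep the groups whole, too few for a share under 0.05. The real split parts all 6 pairs of arrays with the same number, as do 30 of the others, of which the highest gave 3870, and the rest part fewer pairs. The median of the other splits was 0 genes.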
